A study of Homo sapiens with 12 samples.

How the data were processed

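The samples are 6 m1A IP libraries and 6 input libraries of erastin-resistant SNU-668 cells, with 3 ALKBH3 knockdown and 3 control replicates of each kind. Erastin resistance is stated per the labels, whose sample titles also carry a prefix, RLS3, that the labels do not explain and that was left uninterpreted. Per the labels' protocols, mRNA was broken into pieces of about 300 nt, pulled down with an antibody against m1A, made into stranded libraries and sequenced with 150 nt reads. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.32, HISAT2 2.1.0 and the genome build hg19 were used, with no roles stated. The peak caller and its settings are not given in the sources used here. The authors deposited 1 peak list per IP sample, so peaks were called for each replicate and not on pooled samples. Each list has 1 entry per annotated transcript, with the position, the gene, the transcript region and 3 statistics of the peak.

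The enrichment of each peak is a log2 fold change per the file headers, read here as IP over input because every peak value is above 0, although the header does not name its sides. The p-value and false discovery rate of each peak are those the authors deposited, and every deposited p-value lies below 1e-10. These values are the authors' own per peak and were used only to describe, rank or filter peaks within a list. The lists hold no read counts, so the depth of each sample is unknown and the amount of ALKBH3 mRNA was not analysed here. How strongly list length follows from sequencing depth or from the efficiency of the IP could therefore not be measured. Fragments of about 300 nt blur the position of a modified base.

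Entries were collapsed to distinct peaks by chromosome, start and end, and peaks to genes by the deposited gene name. Of the 10226 gene names, 9358 (91.5%) matched a current symbol in a gene name table, and 868 matched none. Between 0.797% and 1.23% of the peaks of a list carried more than 1 gene name. Clustered protocadherins share exons, so that 1 peak there counts for several genes. Positions are printed counted from 1. A peak was assigned to coding sequence, 3′ UTR or 5′ UTR only where all its annotated transcripts gave that region alone. Shares per list have Wilson 95% intervals, which cover counting error only. No pair of lists shared a peak with identical position and enrichment.

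Each list gave 1 value per measure, and groups were compared by a two-sided exact permutation test of the difference in means, with log2 values for numbers of peaks and genes. With 3 lists against 3 the smallest p is 0.1. Genes in all lists of a group and in none of the other were counted and set against the other splits of the 6 lists. Similarity was the Jaccard index over the 15 pairs of lists, for genes and for joined positions. Peaks of all 6 lists that shared at least 1 base on the same strand were joined. A joined position counted for every list with a peak in it, so 2 lists could share it without overlapping directly. An alternative with a reciprocal overlap of at least 50% used bedtools 2.31.1. For 20 gene lists, the share of members with a peak was compared by the same exact test, and members with a peak in at least 2 more lists of a group were tested by Fisher's exact test against all genes with a peak in any list, with Benjamini-Hochberg adjustment over 40 tests. Fisher's test describes these 6 lists, since genes are not replicates. Log2 odds ratios were calculated with a small constant added to every count, so that an empty count still gives a finite value. The gene lists covered ferroptosis suppressors and drivers, glutathione and NRF2 targets, iron handling, fatty acid and sterol synthesis, m1A and m6A machinery, alkylation repair, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, ATF4 and unfolded protein response, autophagy, glycolysis, nuclear oxidative phosphorylation, cell cycle, p53 and apoptosis, epithelial and gastric markers, mesenchymal transition, markers of other cell types and replication dependent histones.

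The genes named in the text are ALKBH3, the 10 genes of each direction and the 8 genes in all lists whose lowest within-list percentile of enrichment was highest, members of the ferroptosis and m1A lists with a difference of at least 2 lists, up to 4 such members of each other list, and SLC7A11, GPX4, ACSL4, TFRC, FTH1, AIFM2 and NFE2L2. Further members of a list were named as examples of a count, chosen after their values were seen, and 4 members are not reported here by name. Groups, tests, gene lists, this rule and the alternatives of the next sentence were set before the data were examined. The alternatives were peaks with at least 4-fold enrichment, a -log10 false discovery rate of at least 5, equal list length (the 4894 most enriched peaks of each list), each replicate left out, replicate number as a block, merged or uncollapsed peaks, autosomes and X alone, other rules of overlap and other backgrounds.

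Added after the data were seen were the number of genes expected from list length and breadth, random gene lists matched on breadth and on transcript length (10000 draws), regions by longest transcript or in genes with a peak in all 6 lists, counts without the longest list of each group, gene families, transcript length, and the search for further red cell and liver mRNAs. In simulated presence of peaks for 9756 genes built on this comparison, 88% of planted genes recurrent in the knockdown lists and 85% of those recurrent in the control lists were found. Called were 2 planted gene lists and 0 of 20 unchanged lists. Planted genes had a peak far more often in 1 group than in the other, and unchanged lists were random genes. These rates do not cover weaker shifts, or gene lists skewed in breadth or transcript length. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.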

Results

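N1-methyladenosine (m1A), a methyl mark on adenine in RNA, was mapped in SNU-668 cells, a human gastric cancer line, that had been made resistant to erastin. Erastin blocks cystine import through the SLC7A11 transporter and causes ferroptosis, a form of cell death driven by iron and lipid peroxidation. The comparison asks how the m1A map of these resistant cells differed after knockdown of ALKBH3, an enzyme that removes m1A from RNA and alkyl damage from DNA, against a control shRNA. The 12 samples comprise 3 immunoprecipitated (IP) and 3 input libraries per group. Each of the 6 IP samples has its own list of m1A peaks in hg19 coordinates, so that every list is 1 replicate. The input libraries entered only through the authors' peak calls. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

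ALKBH3 itself had a peak only in the list of ALKBH3 knockdown replicate 1, in its coding sequence on chromosome 11 (43904645 to 43904694, plus strand), with a log2 enrichment of 2.31. A peak says nothing about the amount of a transcript, so the knockdown could not be checked from these lists. The knockdown lists held 34691, 13056 and 8474 distinct peaks for replicates 1, 2 and 3, and the control lists 5015, 4894 and 15130. The means were 18740 ± 14002 (SD, n = 3) for knockdown and 8346 ± 5875 (SD, n = 3) for control, a 2.18-fold difference in geometric mean (log2 difference 1.12, two-sided exact permutation test, p = 0.3). Genes with a peak numbered 8426, 6003 and 4475 in the knockdown lists and 2804, 2939 and 6019 in the control lists, a 1.66-fold difference in geometric mean (log2 difference 0.73, two-sided exact permutation test, p = 0.3). In both measures the lists of the groups overlapped, and the smallest p this design allows is 0.1. The log2 difference in peaks was 0.55 without ALKBH3 knockdown replicate 1. With every list limited to its 4894 most enriched peaks, the log2 difference in genes was 0.12. That limit makes the numbers of peaks equal, so only peaks per gene, 1.52 to 1.75 across the lists, could still differ. The number of reads behind each list is unknown, so its share in these differences could not be measured.

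**Figure D1:**
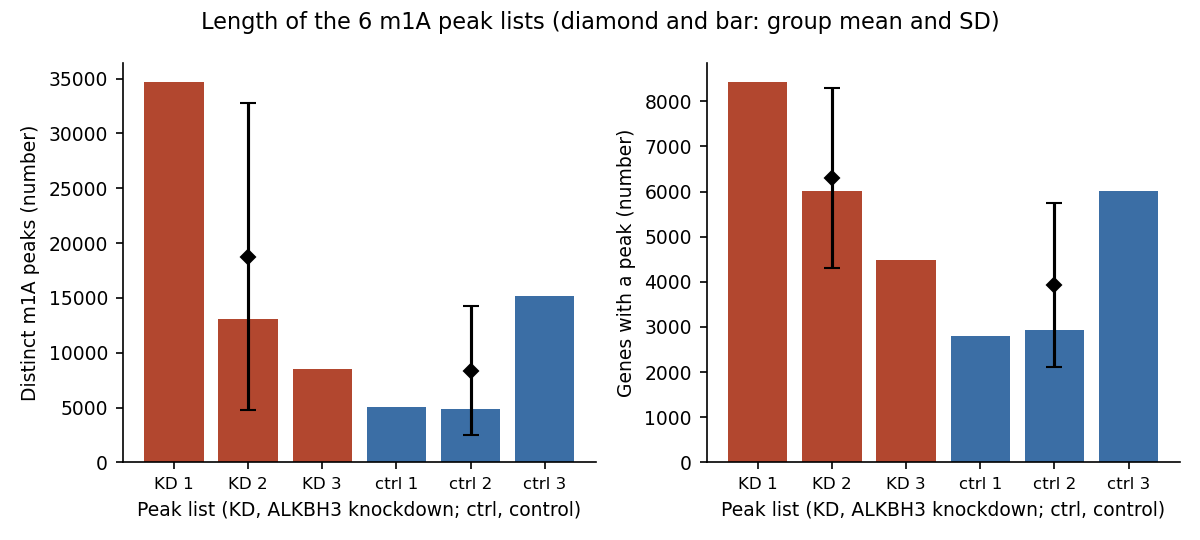
Number of distinct m1A peaks (left axis panel) and of genes with a peak (right axis panel) in each of the 6 lists, with bars for single lists and a diamond with error bar for the mean and SD of 3 lists. ALKBH3 knockdown replicate 1 is the longest list with 34691 peaks, and control replicate 3 with 15130 peaks exceeds the other 2 knockdown lists.

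Of the 10226 genes with a peak in any list, 297 had a peak in all 3 knockdown lists and in no control list, and 4 had the reverse pattern. Among the 297, the 10 with the highest enrichment ranks in every knockdown list were STXBP4, GCNT1, ALKBH8, LMBRD2, CREBRF, DOCK10, TATDN3, ZADH2, REV3L and FAM122A. ALKBH8, a relative of ALKBH3 that modifies the wobble uridine of tRNAs, had its best peak in the 3′ UTR on chromosome 11 in each knockdown list, with log2 enrichments of 4.76 (107374427 to 107374501), 6.42 (107374027 to 107374151) and 4.48 (107373602 to 107373776). REV3L, the catalytic subunit of the translesion DNA polymerase zeta, had its best peak in coding sequence on chromosome 6 in each knockdown list, with log2 enrichments of 4.06, 4.31 and 3.92. The peaks of GCNT1, a glycosyltransferase of mucin-type glycans, lay in the 3′ UTR on chromosome 9, with log2 enrichments of 4.38, 4.96 and 5.60. The 4 genes with a peak in all control lists and no knockdown list were FBXO28, THUMPD2, MED21 and MCTS1. FBXO28, an F-box protein, had log2 enrichments of 2.89, 2.95 and 3.14 in the control lists, and MCTS1, a translation factor, had 1.47, 1.52 and 1.40.

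Peaks of these genes seldom overlapped between replicates. Only 24 of the 297 genes (8.08%) had a base covered by a peak in all 3 knockdown lists. Given only the length of each list and the number of lists in which each gene had a peak, 302.5 ± 16.1 (SD) genes were expected in all knockdown and no control list, and 6.42 ± 2.53 (SD) in the reverse pattern, a calculation added after the data had been seen. Leaving out ALKBH3 knockdown replicate 2, ALKBH3 knockdown replicate 3 or control replicate 3 raised the 297 genes to 545, 868 and 946, and without control replicates 1, 2 or 3 the 4 genes of the reverse pattern became 47, 21 and 12. Without ALKBH3 knockdown replicates 1, 2 or 3 they became 99, 12 and 9. With every list limited to its 4894 most enriched peaks the counts were 154 and 64, and with at least 2 lists against none 1222 and 72. Without the longest list of each group, a choice made after the data had been seen, they were 1113 and 137. The reverse count alone was 7 among peaks with at least 4-fold enrichment and 40 for peak positions in place of genes.

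**Figure D2:**
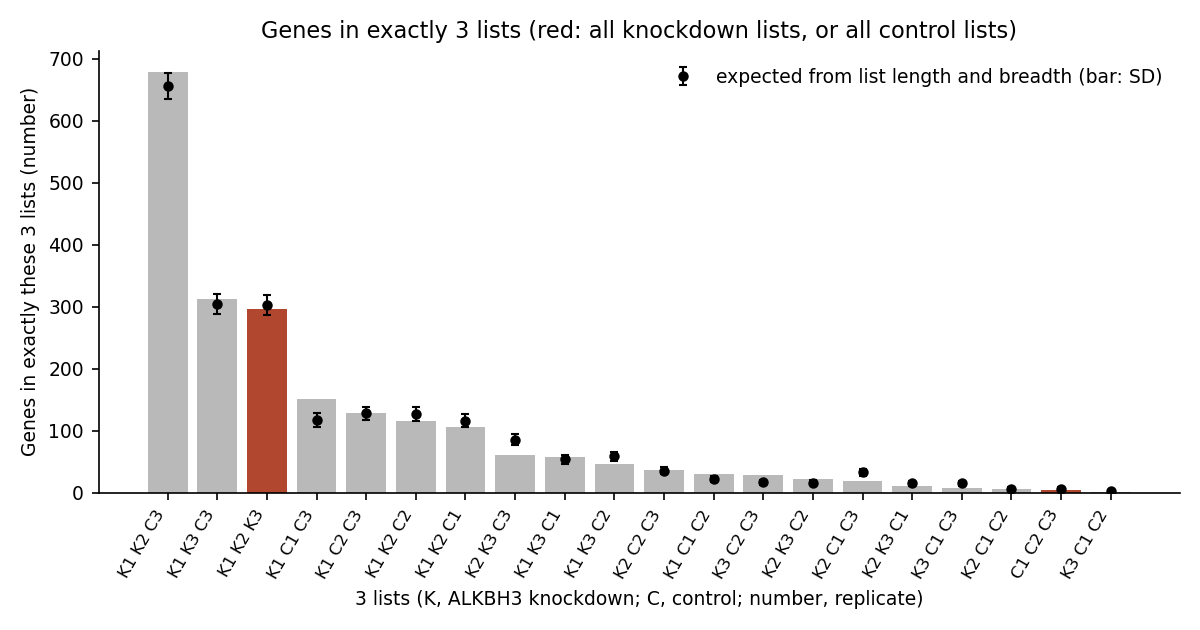
Number of genes with a peak in exactly 3 of the 6 lists (vertical axis), for each choice of 3 lists (horizontal axis), as bars, with the number expected from list length and breadth as points with SD. The 297 genes of the 3 knockdown lists stand below the 679 genes of knockdown replicates 1 and 2 with control replicate 3, and close to the expected 302.5.

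For gene groups, a gene was counted as recurrent in one condition when it had a peak in at least 2 more lists of that condition. By this measure 2055 genes (20.1%) were recurrent in the knockdown lists and 180 (1.76%) in the control lists, where list length and breadth alone gave expected numbers of 2068 and 138. The 180 lay above its expected number, for which no SD was calculated. For some choices of 3 lists the calculation also missed the count. Knockdown replicate 1 with control replicates 1 and 3 shared 152 genes against 117 ± 10.5 (SD). Knockdown replicates 2 and 3 with control replicate 3 shared 61 against 85.6 ± 9.06 (SD). Of 70 named genes recurrent in a group, 31 were no longer so at equal list length and 25 no longer so among peaks with at least 4-fold enrichment. All 26 ferroptosis suppressors had a peak in some list, and 4 of them were recurrent in the knockdown lists. These were NFE2L2, the transcription factor of the antioxidant response, GCLC, the catalytic subunit that limits glutathione synthesis, MBOAT2, a phospholipid acyltransferase, and OTUB1, a deubiquitinase that stabilises SLC7A11. Each had a peak in all 3 knockdown lists and in 1 control list, but NFE2L2 and OTUB1 were not recurrent at equal list length, nor NFE2L2 with at least 4-fold enrichment. MBOAT2 had log2 enrichments of 3.51, 3.38 and 4.37 in the knockdown lists and 3.10 in control replicate 3. The share of 15.4% recurrent in the knockdown lists compared with 20.1% of the other genes (Fisher's exact test, p = 0.806, adjusted p = 1 over 40 tests). None of the suppressors was recurrent in the control lists. Per list, 74.4% ± 9.68 of the suppressors had a peak in the knockdown and 59.0% ± 22.5 in the control lists (SD, n = 3 each; two-sided exact permutation test, p = 0.4, adjusted p = 0.615 over 20 lists). This difference of 15.4 percentage points was 7.05 without control replicate 1 and 28.2 without control replicate 3.

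GPX4, the lipid peroxide reductase, had a peak across its coding sequence and 3′ UTR on chromosome 19 in all 6 lists, with log2 enrichments between 1.16 and 1.64. SLC7A11 had a peak in 3 knockdown and 2 control lists. Its best peak had a log2 enrichment of 6.93 in ALKBH3 knockdown replicate 1 (chromosome 4, 139088376 to 139088425, 3′ UTR), but 2.62 and 1.49 in knockdown replicates 2 and 3. In control replicates 1 and 3 the values were 2.40 and 2.31, and the best peaks lay at different positions. FTH1, the ferritin heavy chain, had a peak in all 6 lists. The best peak of FTH1 reached into its 5′ UTR in 4 lists, such as chromosome 11, 61732922 to 61735080, in ALKBH3 knockdown replicate 2. TFRC, the transferrin receptor, had a peak in all 6 lists, ACSL4, an acyl-CoA synthetase that feeds lipid peroxidation, in 3 knockdown and 2 control lists, and AIFM2, a quinone reductase that protects from ferroptosis, in 1 list of each group. At equal list length ACSL4 had a peak in 2 more control than knockdown lists. That limit keeps control replicate 1 nearly whole, with its ACSL4 peak at a log2 enrichment of 1.56. It drops the stronger ACSL4 peak of ALKBH3 knockdown replicate 1 (2.61), so the change of direction cannot be told apart from this selection.

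Of the 22 ferroptosis drivers with a peak, none was recurrent in either direction. The share of 0 of 22 compared with 20.1% of the other genes recurrent in the knockdown lists (Fisher's exact test, p = 0.0135, adjusted p = 0.179), which did not pass the correction. Among 24 glutathione and NRF2 target genes, 6 were recurrent in the knockdown lists, including GSR, glutathione reductase, and AKR1C2, an aldo-keto reductase with a peak in all knockdown lists and no control list, and PRDX1, a peroxiredoxin, in the control lists. Of 20 iron handling genes, CISD2 and FBXL5, an iron-sensing ubiquitin ligase subunit, were recurrent in the knockdown lists and SLC11A2, an iron importer with a peak in 2 control lists, in the control lists. Of 25 genes of fatty acid and sterol synthesis, 6 including ACSL1 and FADS2 were recurrent in the knockdown lists, and INSIG1, a sterol sensor, in the control lists. CISD2, FBXL5 and ACSL1 were recurrent neither at equal list length nor with at least 4-fold enrichment, FADS2 was not in the former and INSIG1 not in the latter. None of these 3 lists passed Fisher's exact test in either direction.

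Among 12 genes of the m1A machinery with a peak, FTO, YTHDF1 and YTHDC1 were recurrent in the knockdown lists and none in the control lists. FTO, an RNA demethylase, had a peak in 2 knockdown lists, with log2 enrichments of 2.74 and 2.77, and in no control list. Of 20 genes of the m6A machinery, 5 were recurrent in the knockdown lists, among them METTL14, a subunit of the m6A methyltransferase, and RBM15. Of 14 alkylation repair genes, ASCC3, the helicase that works with ALKBH3 in alkylation repair, LIG1 and PARP1 were recurrent in the knockdown lists. ASCC3 had log2 enrichments of 2.72, 3.09 and 4.10 in the knockdown lists and 2.90 in control replicate 3. At equal list length FTO, YTHDF1, YTHDC1, ASCC3 and LIG1 were not recurrent. No list of these 3 passed Fisher's exact test.

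Cytosolic ribosomal protein mRNAs were the only gene list of 20 that passed Fisher's exact test after adjustment, where 4 of 40 tests had an unadjusted p below 0.05. Peaks covered 78, 58 and 63 of the 78 members in the knockdown lists and 73, 76 and 76 in the control lists. None was recurrent in the knockdown lists (Fisher's exact test, adjusted p = 1.45e-06), where 73 or more members in every control list left little room for it. The size of its log2 odds ratio, -5.32, rests on the constant added to the empty count. Recurrent in the control lists were 8 members against 1.69% of the other genes (log2 odds ratio 2.80, Fisher's exact test, adjusted p = 0.00129), among them RPL7, RPL11, RPL19, RPL23A, RPL34, RPS3A and RPS25. RPL11 had log2 enrichments of 1.04, 1.07 and 0.78 in the control lists and 1.61 in ALKBH3 knockdown replicate 1. The mean difference of -0.33 lists per gene lay below that of random gene lists matched on the number of lists with a peak (mean 0.24) and of lists matched also on transcript length (mean 0.13), each with a permutation p of 0.0001, the smallest that 10000 draws allow, in tests added after the data had been seen. The excess in the control lists was lost without ALKBH3 knockdown replicate 1 (log2 odds ratio 1.15) or control replicate 1 (1.79). Without ALKBH3 knockdown replicate 2 or 3 it could not be tested. All 78 members had a peak in ALKBH3 knockdown replicate 1, so no member could then be counted as recurrent in the control lists. The log2 odds ratios there (-1.23 and -0.87) are those of an empty count. Counting only genes with a peak in 3 lists against none could not test either call, since no member could have such a pattern. All members had a peak in ALKBH3 knockdown replicate 1, and none was recurrent in the knockdown lists. The log2 odds ratios there (-2.25 and 3.84, Fisher's exact test, adjusted p = 1 each) are those of empty counts. At equal list length 4 gene lists in place of 1 were over-represented among genes recurrent in the control lists. That limit keeps control replicates 1 and 2 nearly whole and takes weak peaks, such as those of ribosomal protein mRNAs, from the longer lists, so the ribosomal log2 odds ratio of 4.78 there follows from the selection. Among peaks with at least 4-fold enrichment, the mean share of members with a peak was 7.26 percentage points higher in the knockdown lists, the opposite direction to the difference of -11.1 points with all peaks, and RPL11, RPL19, RPL23A and RPL34 were no longer recurrent.

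Nuclear genes of oxidative phosphorylation had a peak for 31, 16 and 12 of 31 members in the knockdown lists and 20, 18 and 22 in the control lists. Genes recurrent in the knockdown lists included NDUFS1 and COX5A, and those in the control lists were the ATP synthase subunits ATP5O and ATP5G2. Their mean difference lay below that of random lists matched on breadth (permutation test, adjusted p = 0.00400), and the call was lost when transcript length was matched too (adjusted p = 0.0750). Of 19 glycolysis genes none was recurrent in the knockdown lists (Fisher's exact test, p = 0.0209, adjusted p = 0.209) and PGAM1, phosphoglycerate mutase, was recurrent in the control lists. NDUFS1 and COX5A were recurrent neither at equal list length nor with at least 4-fold enrichment, and ATP5G2 was not in the latter. Among peaks with at least 4-fold enrichment, ATP5O, PGAM1 and RPL19 each had a peak in 1 more knockdown than control list. All 13 mitochondrially encoded mRNAs had a peak in all 6 lists.

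In the list of ATF4 and unfolded protein response genes, 7 of 22 were recurrent in the knockdown lists, including EIF2AK3, the PERK kinase, with a peak in all knockdown and no control list and log2 enrichments of 3.69, 3.33 and 4.52. ATF3 and ASNS were recurrent in the control lists (2 of 22, Fisher's exact test, p = 0.0565, adjusted p = 0.452). Of 35 cell cycle genes, 4 were recurrent in the knockdown lists, MKI67, CCNE2, MCM2 and MCM4. Of 23 autophagy genes, 5 including ULK1 and LAMP1 were recurrent in the knockdown lists and ATG12 in the control lists. Of 21 genes of the p53 pathway and apoptosis, 4 including APAF1 and CASP8, an initiator caspase, were recurrent in the knockdown lists, and CYCS, cytochrome c, in the control lists. Of 15 mesenchymal genes, CDH2, SNAI1 and MMP2 were recurrent in the knockdown lists, and of 8 epithelial and gastric markers, VIL1. MKI67, MCM4, LAMP1 and CDH2 were recurrent neither at equal list length nor with at least 4-fold enrichment, MCM2, CASP8 and MMP2 were not in the former, and ASNS and CYCS not in the latter. None of these lists passed Fisher's exact test after adjustment.

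Replication dependent histones were the only list in which every knockdown list, with a peak in 9, 5 and 4 of 10 genes, lay above every control list, with 2, 2 and 3 (means 60% ± 26.5 and 23.3% ± 5.77, SD, n = 3 each; two-sided exact permutation test, p = 0.1, adjusted p = 0.615). Chance gives such a separation in 10% of comparisons of 3 against 3. The difference of 36.7 percentage points was 6.67 at equal list length, where the separation was lost (two-sided exact permutation test, n = 3 each, p = 0.9), and 21.7 without ALKBH3 knockdown replicate 1. The 4 histone genes recurrent in the knockdown lists were HIST1H1E, HIST1H2AC, HIST1H4H and HIST2H2BE, and none of them was at equal list length. The mean share was higher in the knockdown lists for 16 of the 20 lists, and no list passed the exact test after adjustment. With every list limited to its 4894 most enriched peaks, the difference turned negative for 12 lists, among them both ferroptosis lists, a setting that removes weak peaks mainly from the longer lists.

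**Figure D3:**
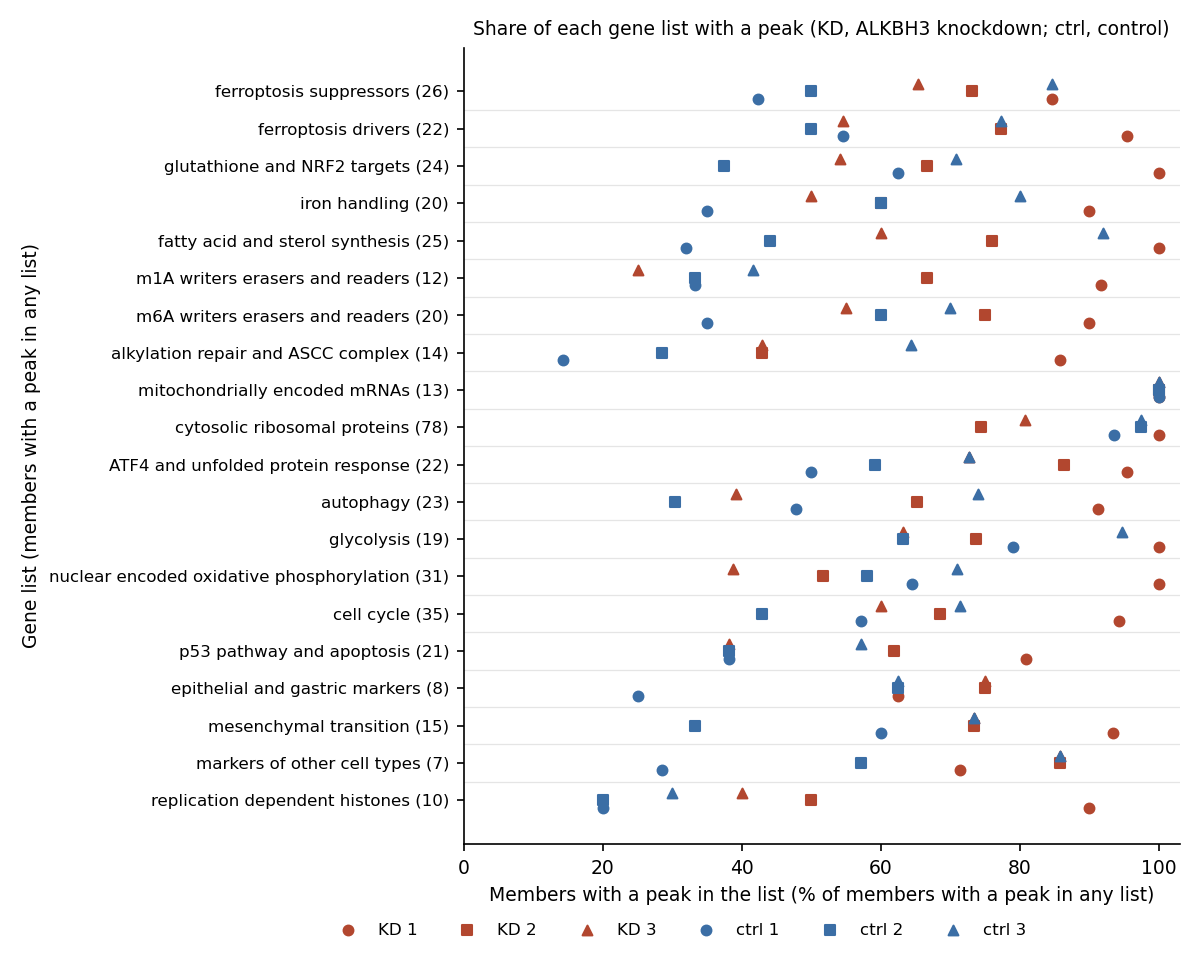
Share of the members of each fixed gene list that had a peak in each of the 6 peak lists (horizontal axis, percent of members with a peak in any list, number in parentheses), with red symbols for ALKBH3 knockdown and blue symbols for control and the replicate by shape. Ribosomal protein mRNAs lie above 90% in all control lists and at 74.4% and 80.8% in knockdown replicates 2 and 3, while most other lists are highest in knockdown replicate 1.

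Globin or albumin genes held the most enriched peak of 5 of the 6 lists. Of 25 markers of other cell types in the gene list, 7 had a peak. The alpha globin genes HBA1 and HBA2, which encode haemoglobin chains of red blood cells, had peaks in all 3 knockdown lists and in control replicates 2 and 3. On chromosome 16, the HBA2 peak (223171 to 223703 in control replicate 3) had log2 enrichments of 9.68, 10.41 and 10.44 in the knockdown lists and 9.99 and 12.74 in those control lists. The copies are nearly identical, so reads cannot be assigned to HBA1 or HBA2 with certainty. HBB, beta globin, had a log2 enrichment of 7.46 in ALKBH3 knockdown replicate 3 and 13.18 in control replicate 3. ALB, serum albumin, had a peak in coding sequence at 74274402 on chromosome 4 in ALKBH3 knockdown replicates 2 and 3, with log2 enrichments of 13.25 and 9.51, and in no control list. HBA1, HBA2 and HBB are named here because of their values. Among the same top 5 peaks, KRT19 and EPCAM, both epithelial genes, had log2 enrichments of 9.22 and 8.68 in control replicate 2, and FOLR1, a folate receptor, 10.01 in control replicate 3, and these were likewise chosen after their values were seen.

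Peaks lay in coding sequence more often in the knockdown lists. The share of peaks within coding sequence in every annotated transcript was 55.7%, 45.3% and 39.9% in the knockdown lists and 26.0%, 25.3% and 37.7% in the control lists (means 46.9% ± 8.07 and 29.7% ± 6.97, SD, n = 3 each). The share within the 3′ UTR was 19.7%, 39.2% and 44.1% in the knockdown lists and 57.5%, 59.6% and 44.3% in the control lists (means 34.4% ± 12.9 and 53.8% ± 8.28, SD, n = 3 each). Every knockdown value lay above every control value for coding sequence and below it for the 3′ UTR (two-sided exact permutation test, p = 0.1 each, the smallest possible, adjusted p = 0.367 over 11 features). The 3′ UTR separation rests on ALKBH3 knockdown replicate 3 and control replicate 3, whose Wilson intervals overlap, and was lost among genes with a peak in all 6 lists (difference -16.3 percentage points, two-sided exact permutation test, n = 3 each, p = 0.2). Without ALKBH3 knockdown replicate 1 the 3′ UTR difference of -19.5 percentage points was -12.2. The 5′ UTR held 2.94% ± 0.353 and 2.11% ± 0.750 of peaks (SD, n = 3 each; two-sided exact permutation test, p = 0.2). Median transcript length per peak was 3923 ± 158 nt in the knockdown lists and 3418 ± 214 nt in the control lists, again without overlap (SD, n = 3 each; two-sided exact permutation test, p = 0.1). This difference of 506 nt was 862 nt at equal list length and 302 nt among peaks with at least 4-fold enrichment, where the groups overlapped (two-sided exact permutation test, n = 3 each, p = 0.2). Equal length kept control replicates 1 and 2 nearly whole (3266 and 3448 nt). It cut the other lists to their most enriched peaks, whose median was higher in each. Control replicate 3 rose from 3615 to 4360 nt and ALKBH3 knockdown replicate 1 from 3755 to 4387 nt. The 862 nt cannot be told apart from this selection. Wilson 95% intervals of the shares per list reached at most 1.37 percentage points to either side, and they cover counting error only.

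**Figure D4:**
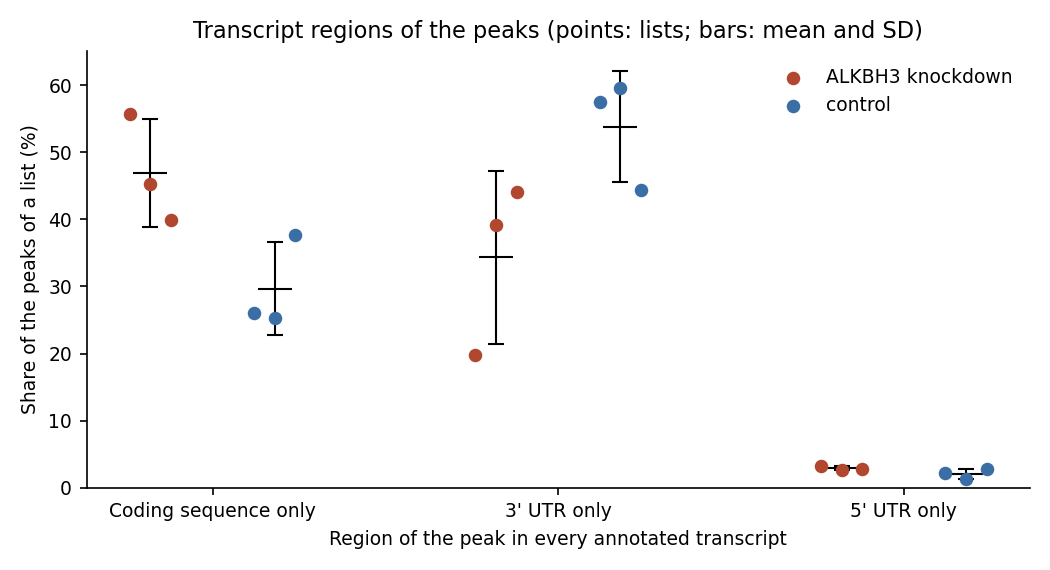
Share of the peaks of each list (vertical axis, percent) that lay only in coding sequence, only in the 3′ UTR or only in the 5′ UTR of all annotated transcripts, with a point per list and the mean and SD of 3 lists per group. The knockdown lists lie between 39.9% and 55.7% for coding sequence, and the control lists between 25.3% and 37.7%.

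Other peak features overlapped between the groups. The median log2 enrichment was 2.13 ± 0.15 in the knockdown and 1.97 ± 0.35 in the control lists (SD, n = 3 each; two-sided exact permutation test, p = 0.6), and the median peak length 83.3 ± 14.4 nt and 66.7 ± 14.4 nt (SD, n = 3 each; two-sided exact permutation test, p = 0.6). Peaks on the mitochondrial genome numbered 17.3 ± 4.16 and 12 ± 2 (SD, n = 3 each; two-sided exact permutation test, p = 0.2), and peaks per gene 2.73 ± 1.21 and 1.99 ± 0.458 (SD, n = 3 each; two-sided exact permutation test, p = 0.5). The difference in peaks per gene rests mainly on ALKBH3 knockdown replicate 1. The values were 4.12, 2.17 and 1.89 in the knockdown lists and 1.79, 1.67 and 2.51 in the control lists. The difference in median log2 enrichment turned without control replicate 1 (-0.0288), and at equal list length the differences in mitochondrial peaks (-8.33) and in peaks per gene (-0.138) turned.

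A peak at any position was present in all 6 lists for 772 genes, while 369 joined peak positions were present in all 6 lists. The 8 with the highest ranks in every list were TAPBP, KRT8, EIF2AK2, KIAA1191, EHD2, DDOST, PHLDA1 and BTAF1. TAPBP, the tapasin chaperone of antigen presentation, had 3′ UTR peaks on chromosome 6 near 33268246 in all lists, with log2 enrichments between 4.13 and 6.42. KRT8, keratin 8, had log2 enrichments between 4.07 and 6.32, and EIF2AK2, the PKR kinase, between 3.10 and 5.27. The Jaccard index of genes averaged 0.391 within groups and 0.370 between groups (exact permutation test over the 10 splits, n = 6 lists, p = 0.4), and the highest value, 0.579, joined ALKBH3 knockdown replicate 1 and control replicate 3. For joined peak positions the averages were 0.0902 and 0.0861 (exact permutation test, n = 6 lists, p = 0.7). The difference for genes, 0.0214, was 0.0381 at equal list length and 0.118 without control replicate 3. Its direction turned for genes without ALKBH3 knockdown replicate 1 (-0.0120), 2 (-0.0249) or 3 (-0.00457) and with the overlap over the smaller list (-0.0102), and for positions without control replicate 1 (-0.00436) or 2 (-0.00571).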

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

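Counts without the longest list of each group, regions by another assignment or in genes with a peak in all 6 lists, and random gene lists were chosen after the data were seen, and all other alternatives here were planned. Differences in the number of peaks and genes, in the coding, 3′ UTR and 5′ UTR shares, and the share of ribosomal protein genes among genes recurrent in the knockdown lists kept their direction under the alternatives run, but not their size. The log2 difference in peaks (1.12) ranged from 0.55 to 1.66 without 1 list, and that in genes (0.73) from 0.50 to 1.09. At equal list length the log2 difference in genes was 0.12, a setting that makes the numbers of peaks equal and so nearly fixes the numbers of genes. In percentage points, the coding difference (17.3) ranged from 12.9 to 21.3, the 3′ UTR difference (-19.5) from -24.3 to -12.2 and the 5′ UTR difference (0.833) from 0.434 to 1.18 without 1 list, and at equal length these 3 were 11.7, -12.9 and 1.61. Among genes with a peak in all 6 lists the 3′ UTR difference was -16.3, where the groups overlapped. A false discovery rate filter (-log10 of at least 5) removed 0 peaks. Leaving out 1 list lowers the number of lists a gene must be in, which raises the counts by construction: genes in all knockdown and no control list, 297 with all lists, ranged from 385 to 946, and the reverse, 4 with all lists, from 9 to 99. At equal list length these counts were 154 and 64, with at least 2 lists against none 1222 and 72, and without the longest list of each group 1113 and 137. The reverse count was 7 with at least 4-fold enrichment and 40 for peak positions in place of genes. Within minus between similarity ranged over left-out lists from -0.0249 to 0.118 for genes and from -0.00571 to 0.0211 for positions, and was -0.0102 with the overlap over the smaller list. With 3 lists against none, 0 gene lists were under-represented among knockdown genes and 0 over-represented among control genes. The ribosomal log2 odds ratios of -2.25 and 3.84 there (Fisher's exact test, adjusted p = 1 each) come from counts of 0 members. No other ribosomal count was possible in this setting, so it could not test these calls. Over-represented among control genes were 4 gene lists at equal length and 0 to 1 without 1 list. In mean difference, 2 lay below random lists matched on breadth. Without knockdown replicate 2 or 3 the ribosomal count was fixed at 0, as all members had a peak in knockdown replicate 1. Over all left-out lists, these 2 included, the ribosomal log2 odds ratio (2.80 with all lists) ranged from -1.23 to 2.98. At equal length this ratio was 4.78 and the ribosomal share difference -56.4 percentage points, against -11.1 with all peaks, which follows from selection by enrichment, since it keeps control replicates 1 and 2 nearly whole and removes weak peaks from the longer lists. At equal list length the difference in mean share (percentage points) became negative for ferroptosis suppressors (-8.97), ferroptosis drivers (-25.8), glutathione and NRF2 targets (-9.72), iron handling (-21.7), fatty acid and sterol synthesis (-16.0), m1A machinery (-5.56), m6A machinery (-8.33), ATF4 and unfolded protein response (-15.2), autophagy (-13.0), cell cycle (-20.0), p53 and apoptosis (-9.52) and mesenchymal genes (-4.44), as did peaks per gene (-0.138) and mitochondrial peaks (-8.33). With at least 4-fold enrichment it turned for iron handling (-1.67), ribosomal proteins (7.26) and oxidative phosphorylation (10.8). Without 1 list it ranged from -3.33 to 19.2 for iron handling and from -19.4 to 11.3 for oxidative phosphorylation, the median log2 enrichment difference from -0.0288 to 0.305 and that of peaks with 4-fold enrichment from -0.883 to 14.6 percentage points, and at equal length, which selects on enrichment itself, these 2 were 0.744 and 35.1. The difference in lists with a peak turned for ATP5O, PGAM1 and RPL19 (1 each with at least 4-fold enrichment). At equal length, which removes weak peaks mainly from the longer lists, it turned for NBR1 (-1) and ACSL4 (-2, from 1 with all peaks). Of 70 named genes recurrent in a group, 31 were no longer so at equal length and 25 with at least 4-fold enrichment. The cause of the other changes was not tested. With replicate number as a replicate block the log2 difference in peaks was 1.12 (exact sign-flip test of 3 pairs, p = 0.5, smallest possible 0.25) and in genes 0.73 (p = 0.5), and same-numbered lists correlated at 0.0366, 0.0413 and -0.0114, so the numbers do not pair the lists. Read depth is unknown, so its effect could not be measured.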

Other observations

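The tests in this part were chosen after the results were seen, with these exceptions. Equal list length, the other splits of the lists and the shares of peaks per chromosome were planned. The rules for reading equal list length and the splits were written later. Predictions for the comparison of long with short transcripts and for the search for further red cell and liver mRNAs were written before their results. Gene families outside the 20 gene lists were compared with random gene lists matched on the number of lists with a peak. Of 18 families, only ATPase and ATP synthase subunits passed (54 genes, a mean of -0.45 lists relative to random lists, permutation test, adjusted p = 0.0126), and the call was lost when transcript length was matched too (adjusted p = 0.0702). Kinesins, the motor proteins of microtubules, had 12 of 29 genes recurrent in the knockdown lists and 0 in the control lists (adjusted p = 0.0846, permutation test). Centrosomal CEP genes had 13 of 30 and 0 (adjusted p = 0.114, permutation test). Over all genes, 20.1% were recurrent in the knockdown lists and 1.76% in the control lists. With transcript length matched too, the adjusted p was 0.197 for kinesins and 0.387 for CEP genes (permutation test). Of 22 protocadherin names, 21, 21 and 0 had a peak in the knockdown lists and 0, 0 and 20 in the control lists.

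Genes with long transcripts were more often recurrent in the knockdown lists. Of the shortest of 5 equal groups (45 to 1832 nt), 266 of 2046 genes were recurrent in the knockdown lists and 48 in the control lists, and of the 2044 in the longest group (5504 nt or more), 596 and 19. Per list, the log2 ratio of the share with a peak in the longest to that in the shortest group was 0.43 ± 0.48 in the knockdown and -0.06 ± 0.30 in the control lists (SD, n = 3 each; two-sided exact permutation test, p = 0.3). Chromosomes 5, 7 and 12 held a smaller share of peaks in every knockdown list than in every control list, such as 5.43% ± 0.489 against 6.78% ± 0.867 for chromosome 12 (SD, n = 3 each; two-sided exact permutation test, p = 0.1, adjusted p = 0.800 over 24 chromosomes), where chance gives such a separation for 10%. Chromosome Y had 7 genes with a peak in a knockdown list and 0 with a peak in a control list (probability 0.00537 from list length and breadth alone, 0.134 over the 25 chromosomes looked at), and sample identity was not tested.

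Genes with a peak in all knockdown lists and no control list (297) far outnumbered the reverse (4). A difference in list length may account for this excess by itself, since a calculation from list length and breadth alone expected 302.5 such genes. Of the 10 splits of the 6 lists, 3 gave as many genes that separate the sides, with 301 in the real split and 680 in the highest other, and 10 splits are too few for a share under 0.05. The larger split placed control replicate 3, the longest control list, with ALKBH3 knockdown replicates 1 and 2, a structure of the lists by their length. Whether the lists differ in length through ALKBH3, read depth or the yield of the IP stays open.

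The higher coding share in the knockdown lists remained at equal list length. The difference there was 11.7 percentage points against a spread of 3.54 (pooled SD). That limit keeps the shorter control lists nearly whole and cuts the others to their most enriched peaks. With the cut, the coding share of the longest knockdown list fell from 55.7% to 42.3%. That of the longest control list fell from 37.7% to 24.4%. The setting therefore cannot separate list length from group. Among genes with a peak in all 6 lists the difference was 12.8 points, too close to the bound set for it to tell how much a change in the genes contributes. A candidate explanation is a stronger 3′ bias of the control libraries, as degraded RNA can give, and among genes in all 6 lists the difference was 17.9 points for the longest and 2.75 points for the shortest of 3 equal groups by transcript length, a gap of 15.1 points that is larger than the spread of 8.38 (pooled SD). The gap arose in the knockdown lists (34.9% and 50.9% for the shortest and longest group), while the control lists stayed flat (32.2% and 33.0%), so it does not tell a bias in one group from a difference in the other. List length, the 3′ bias and an effect of ALKBH3 on where m1A lies all stay open. The last was not tested, since coverage of the input libraries was not analysed here.

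Globin or albumin mRNAs held the most enriched peak of 5 of the 6 lists of this gastric cancer line. RNA of blood or liver in the IP libraries is a candidate source, and 0 of 18 other abundant red cell and liver mRNAs had a peak among the top 1% of a list, or in any list. An mRNA present at similar levels in IP and input gives no peak, so absence from a peak list cannot exclude RNA shared by both. That reason does not cover RNA in the IP libraries alone, and the globin and albumin peaks had fold enrichments between 176 and 9771. For such RNA the predicted peaks of other red cell and liver mRNAs were not found. How abundant those mRNAs would be is not known here, so the source cannot be told apart from transcription in these cells. Alpha globin peaks were in 3 knockdown and 2 control lists, so they did not follow the groups. A mixture of reads between libraries of different origin was not tested.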
